A study of Mus musculus with 192 samples.

How the data were processed

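Lineage-negative, GFP-positive cells were sorted from dorsal wounds of WT and EKO mice, and 96 TaqMan assays were run on each cell, per the labels. The authors deposited 1 table for the whole series with a row per assay and a column per cell. The table does not name its unit: the values were read as raw Ct, since they run from 4.49 to 40 with none higher, 12852 of the 18432 are exactly 40, and the deposited table is described as not normalized. A Ct is the cycle at which a reaction crosses a fluorescence threshold. The instrument software, the threshold, the number of preamplification cycles and the rule for failed reactions are not given in the sources used here. The antigens of the lineage gate, the day after wounding and the number of animals are not given there either. Genotype and cell number came from the labels, and the letter that opens each cell's title gave the set. The labels speak of each chip, so sets were treated as chips, and each value was also computed within set A and set B. No column of values was left unused, and 0 pairs of cells had identical values.

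Gene names in the table were matched to current mouse symbols in a RefSeq gene table of the GRCm38.p6 assembly, used only for names. Of the 96 names, 89 matched a symbol and 4 a synonym, and 3 (Dppiv, Fox03 and Rn18s) were kept as written. Dppiv was therefore not counted in the Cxcl12 axis list. The panel holds 2 assays for Cxcl12, which are named by their identifiers. Cxcr7 in the table is printed as Ackr3, Tie2 as Tek, Emr1 as Adgre1 and Ctgf as Ccn2. No genome coordinates were used.

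A reaction counted as detected at a Ct below 40. Cells that detected at least 10% of the assays, which is 10 of 96, were kept: 93 WT (48 in set A, 45 in set B) and 77 EKO (39 and 38). For each assay the share of kept cells that detected it was taken per genotype with an exact Clopper-Pearson 95% interval, and the difference was EKO minus WT in percentage points. A share of 0 was given the upper limit that 3 counts allow. The level of a gene was the median Ct over detecting cells with its SD, without normalization to a reference gene. The number of cells limits the precision: a share near 50% of 77 cells has an interval of 39 to 62.2%. Cells of a genotype were not treated as replicates, so no p-value or standard error was computed, and the counts given are of assays that met a size rule and not of genes shown to change.

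Genes to be named, 18 gene lists, 7 sets of cell type markers and the alternatives below were fixed before the data were examined. Named genes were up to 10 each way with the largest share difference of at least 10 points and the same sign in both sets, and up to 4 each way with the largest difference of the median Ct. The latter needed at least 1 cycle, the same sign in both sets and at least 10 detecting cells per genotype and set, and reference genes were left out. Every measured gene of the Cxcl12 axis and up to 3 examples per list with the largest absolute share difference were added, and 1 gene that met the share rule is not reported here. For the 13 lists with at least 3 measured assays, the median difference was placed among 10000 random lists of the same size drawn from the same 3 bins of detection share. A class of cells was a count of at least 2 detected markers.

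The alternatives were Ct limits of 35, 30 and 28, no filter on cells, a filter at 25% of assays (24 of 96), only cells that detect a reference gene, each set alone, and weights that give both genotypes the same spread over terciles of assays detected within a set. For levels they were subtraction of the mean of the detected reference genes or of each cell's own median, the mean in place of the median, failed reactions counted at 40, a Ct limit of 30 and no filter. The requirement of both Actb and B2m, the 25% filter for levels, and a mesenchymal class that counts Col1a1 and Col3a1 only below Ct 16, were chosen after seeing the data. The functions were tested on simulated data: in 50 draws of 96 assays for the comparison of WT with EKO, with 10 assays set 30 points higher in EKO, the mean recovered difference was 30.1 points, and a set Ct difference of -2 was recovered as -1.99. The size rule took up 99.2% of the changed and 6.4% of the unchanged assays. Each assay was drawn independently of the others in a simulated cell, so simulated cells did not vary in yield as the real ones do. The 6.4% is therefore not the rate at which unchanged assays meet the rule in these data. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.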

Results

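Single cells that reached skin wounds from the circulation of a joined donor mouse were compared between wild-type (WT) recipients and recipients that lack the chemokine Cxcl12 in their endothelium (EKO). Each recipient mouse was joined by parabiosis, a surgical union of the circulations of 2 mice, to a donor that expresses green fluorescent protein (GFP). Cells were sorted from dorsal wounds as lineage-negative and GFP-positive, the label of the donor, and the genotype names the recipient. No assay on the panel reads GFP, so the origin of a cell rests on the sort. Microfluidic quantitative PCR read 96 TaqMan assays for 95 genes in each of 192 cells, 96 per genotype, in 2 sets named A and B with 48 cells of each genotype per set. The deposited value is the cycle threshold (Ct), where a lower Ct is a higher level and 1 cycle is about one doubling.

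The 192 cells gave 18432 reactions, of which 5580 amplified at a Ct between 4.49 and 37.9, with a median of 18.5. The other 69.7% stand at 40 and were read as not detected. Rn18s, the 18S ribosomal RNA, was detected in all 192 cells. Ephb4, Etv2, Pou5f1 and Shh were detected in 0 of 192 cells, which allows a share of up to 1.56%. Cells detected between 4 and 70 assays each, and 97 of the 192 detected fewer than 24. No label names an animal, so each genotype counts as 1 sample with no replicate check. Shares carry exact (Clopper-Pearson) 95% intervals that cover counting error only, Ct values carry SDs over cells, and no difference was tested. On each set the WT cells bear the numbers 1 to 48 and the EKO cells 49 to 96, so genotype cannot be told apart from a cell's position in its set.

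The purpose of the comparison was to characterise the progenitor cells recruited to wounds with and without endothelial Cxcl12. Cxcr4, the receptor through which Cxcl12 attracts blood progenitors, was detected in 30 of 77 cells from EKO recipients (38.96%, 95% interval 28.1 to 50.7%) and in 24 of 93 from WT recipients (25.8%, 17.3 to 35.9%). The difference was 13.9 percentage points in set A and 12.4 in set B, and the 2 intervals overlapped. Ackr3, the scavenging receptor for Cxcl12, was detected in 36.4% of EKO and 29.03% of WT cells, with -2.08 points in set A and 17.3 in set B, and -9.07 points among cells with at least 24 assays. Because the cells were sorted for the label of the donor, their own Cxcl12 does not check the recipient's genotype. Of the 2 Cxcl12 assays, Mm00445552_m1 was detected in every kept cell and in the 22 cells the filter left out, and its median Ct was 17.9 ± 1.42 (SD) in WT and 17.7 ± 1.50 in EKO cells. Mm00457276_m1 was detected in 8 WT cells (8.60%, 3.79 to 16.2%) and 13 EKO cells (16.9%, 9.31 to 27.1%). Its difference was -1.76 points in set A and 18.8 in set B. Among the cells called collagen-high below it was more often detected in EKO in both sets, with overlapping intervals. Among cells with at least 24 assays detected, the Cxcr4 difference was 26.7 points in set A and -3.57 in set B.

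The median kept cell from EKO recipients detected more of the panel than that from WT recipients. By share of detecting cells, Notch1, Pik3r1, Icam1 and Bcl2 stood furthest above. The median EKO cell detected 34 assays and the median WT cell 21, among the 77 EKO and 93 WT cells that detected at least 10 of the 96 assays. Over the 96 assays the median difference in detecting cells, EKO minus WT, was 5.70 percentage points. In both sets 43 assays had a higher share in EKO, 6 had a lower one (B2m, Cd55, Col1a1, Hif1a, Tert and Wnt10b), and 47 were mixed or equal. The filter removed 19 EKO cells and 3 WT cells, and with no filter the medians were 28 assays in EKO and 20 in WT. Of the deposited cells, 53 EKO (55.2%, 44.7 to 65.4%) and 42 WT (43.8%, 33.6 to 54.2%) detected at least 24 assays, with medians of 45 and 46.5 assays. Among these the median difference over assays was -0.07 points, with 14 assays higher and 21 lower in EKO in both sets. Deposited cells under 24 assays had medians of 11 assays in EKO and 16.5 in WT.

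**Figure D1:**
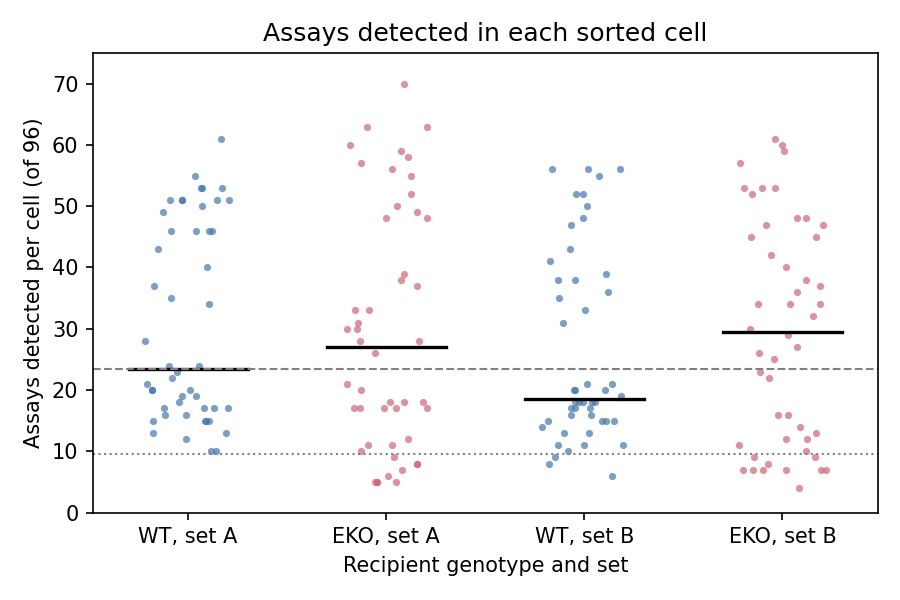
Number of assays detected in each of the 192 sorted cells (points) by recipient genotype and set, with the median as a black line; the dotted and dashed lines mark the limits of 10 and 24 assays. Cells spread from 4 to 70 assays, and 19 EKO cells and 3 WT cells lie below the dotted line.

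The 10 genes with the largest difference in detecting cells were led by Notch1, Pik3r1, Icam1 and Bcl2, each more often detected in EKO. Notch1, a receptor that sets cell fate in blood and vessels (assay Mm00435249_m1), was detected in 39 of 77 EKO cells (50.6%, 39 to 62.2%) against 23 of 93 WT cells (24.7%, 16.4 to 34.8%). Pik3r1, the regulatory subunit of phosphoinositide 3-kinase (Mm00803160_m1), was detected in 66.2% (54.5 to 76.6%) against 40.9% (30.8 to 51.5%). Icam1, an adhesion molecule for leukocytes (Mm00516023_m1), reached 59.7% (47.9 to 70.8%) against 36.6% (26.8 to 47.2%). Bcl2, an inhibitor of apoptosis (Mm00477631_m1), reached 40.3% (29.2 to 52.1%) against 17.2% (10.2 to 26.4%). At the 10-assay filter the intervals of the genotypes did not overlap for these 4 genes, and the differences were 25.9, 25.4, 23.2 and 23.1 points. These genes were picked by the size of their difference in these same cells, so the gap between intervals is not a test. The filter left out 19 EKO and 3 WT cells. Of these 22 cells 0 detected Notch1 or Bcl2, 1 detected Icam1 and 2 detected Pik3r1. Counting them would therefore narrow each of the 4 differences.

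Also among these genes were the Wnt mediator Ctnnb1 (19.2 points), the phagocytosis inhibitor Cd47 (18.96), the metalloproteinase inhibitor Timp1 (17.3), the leukocyte protein Cd48 (17.1) and the growth factor receptor Igf1r (17.1), all higher in EKO in set A and in set B. In all, 20 assays met the rule of at least 10 points with the same sign in both sets, each of them higher in EKO, and 0 were lower. The same rule among cells with at least 24 assays was met by 4 assays higher in EKO (Bcl2, Icam1, Mcam and Wnt3a) and 11 lower (Ccl2, Cd55, Col1a1, Col1a2, Fgfr2, Igf1, Itga5, Klf4, Ly6a, Tek and Wnt10b). Bcl2 stood there at 15.7 points, with 23.2 in set A and 3.57 in set B, and Icam1 at 10.7, with 17.5 and 2.78. Notch1 was 34.7 points higher in set A there and -5.56 in set B, and Pik3r1, Cd47, Timp1, Cd48, Ctnnb1 and Igf1r differed by 8.13 points or less. In those cells Cd55, which restrains complement, was detected in 39.6% of EKO and 61.9% of WT cells, and Col1a1 in 66.04% and 80.95%.

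**Figure D2:**
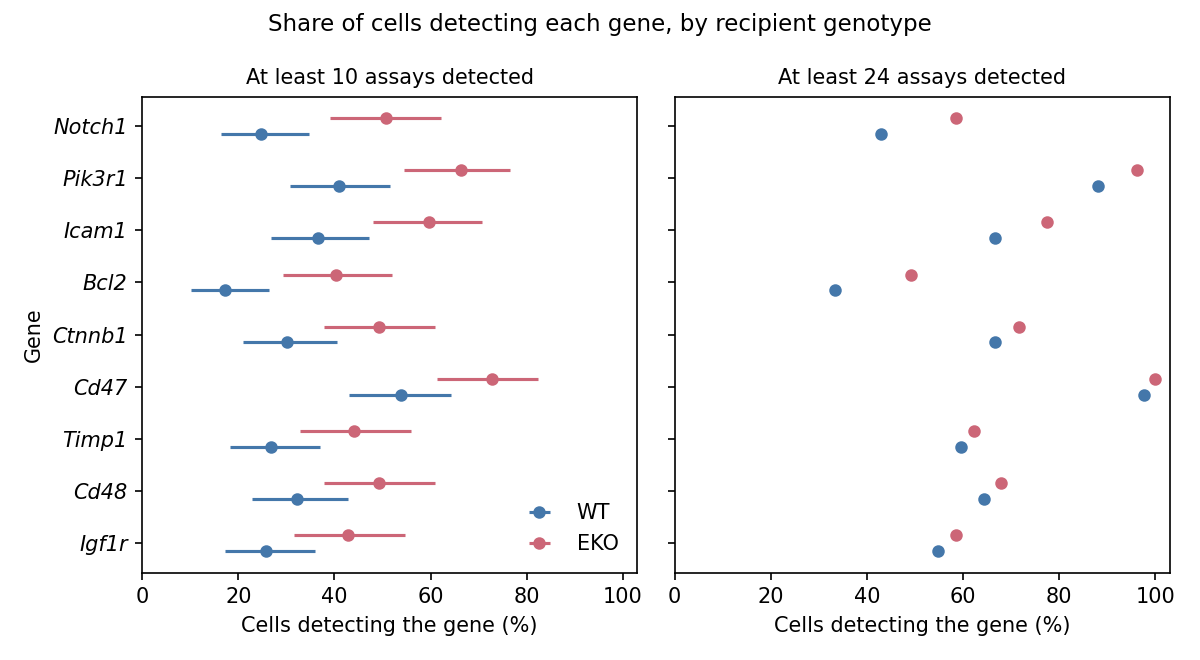
Share of cells (percent) detecting each of 9 of these genes, in WT and EKO recipients; the left panel holds the 93 WT and 77 EKO cells with at least 10 assays detected and exact 95% intervals, and the right panel the 42 WT and 53 EKO cells with at least 24. The gap for Pik3r1 is 25.4 points on the left and 8.13 on the right.

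Among cells that detected a gene, Eng and Igf1r stood at a higher level in EKO and Cd34 and Dppiv at a lower level. Eng, a co-receptor for transforming growth factor beta (Mm00468256_m1), had a median Ct of 19.7 ± 1.92 (SD, 26 cells) in EKO and 22.9 ± 2.10 (26 cells) in WT, a difference of -3.12 cycles. Igf1r, the receptor of insulin-like growth factor 1, had 17.8 ± 1.62 (33 cells) and 20.6 ± 1.77 (24 cells), a difference of -2.75 cycles, with -2.68 in set A and -2.99 in set B. Cd34, a surface protein of blood and vascular progenitors (Mm00519283_m1), differed the other way, with 17.9 ± 2.19 (31 cells) in EKO and 15.3 ± 1.69 (24 cells) in WT. Its Ct was later in EKO by 1.54 cycles in set A and 3.05 in set B. Dppiv (Mm00494538_m1, the name in the file) stood at 19.9 ± 1.39 in 33 EKO cells and 18.2 ± 2.39 in 31 WT cells, a difference of 1.68 cycles. Within the cell classes defined below the Dppiv difference was not steady over the sets. It was 0.38 cycles in set A and 3.07 in set B for collagen-high cells, and -0.41 and 2.23 for Ptprc-detecting cells.

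The chemokine Ccl2 (Mm00441242_m1) and the stem cell antigen Ly6a (Mm00726565_s1) also had earlier median Ct values in EKO, with differences of -4.23 and -4.22 cycles. Col3a1, a fibrillar collagen (Mm01254473_m1), and Cd55 (Mm00438377_m1) had later ones, by 3.49 and 1.37. In EKO and WT cells the SDs were 3.57 and 4.27 cycles for Ccl2, 4.25 and 5.55 for Ly6a and 5.96 and 5.46 for Col3a1, whose values form an early and a late group. Col3a1 was also detected in 10 of the 22 cells that the filter left out, at a median Ct of 19.7. Among cells with at least 24 assays the differences of Ccl2 and Ly6a were -1.11 and -0.83 cycles, and those of Eng and Igf1r were -2.95 and -2.91. Of 47 assays with a level in each genotype and set, 16 met the rule with an earlier Ct in EKO and 4 with a later one. Actb and B2m, 2 reference genes, were also earlier in EKO, with differences of -1.90 and -1.31 cycles. Taking each cell against its own median over detected genes left Eng at -1.82, Igf1r at -2.83, Cd34 at 2.86 and Dppiv at 0.98 cycles.

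**Figure D3:**
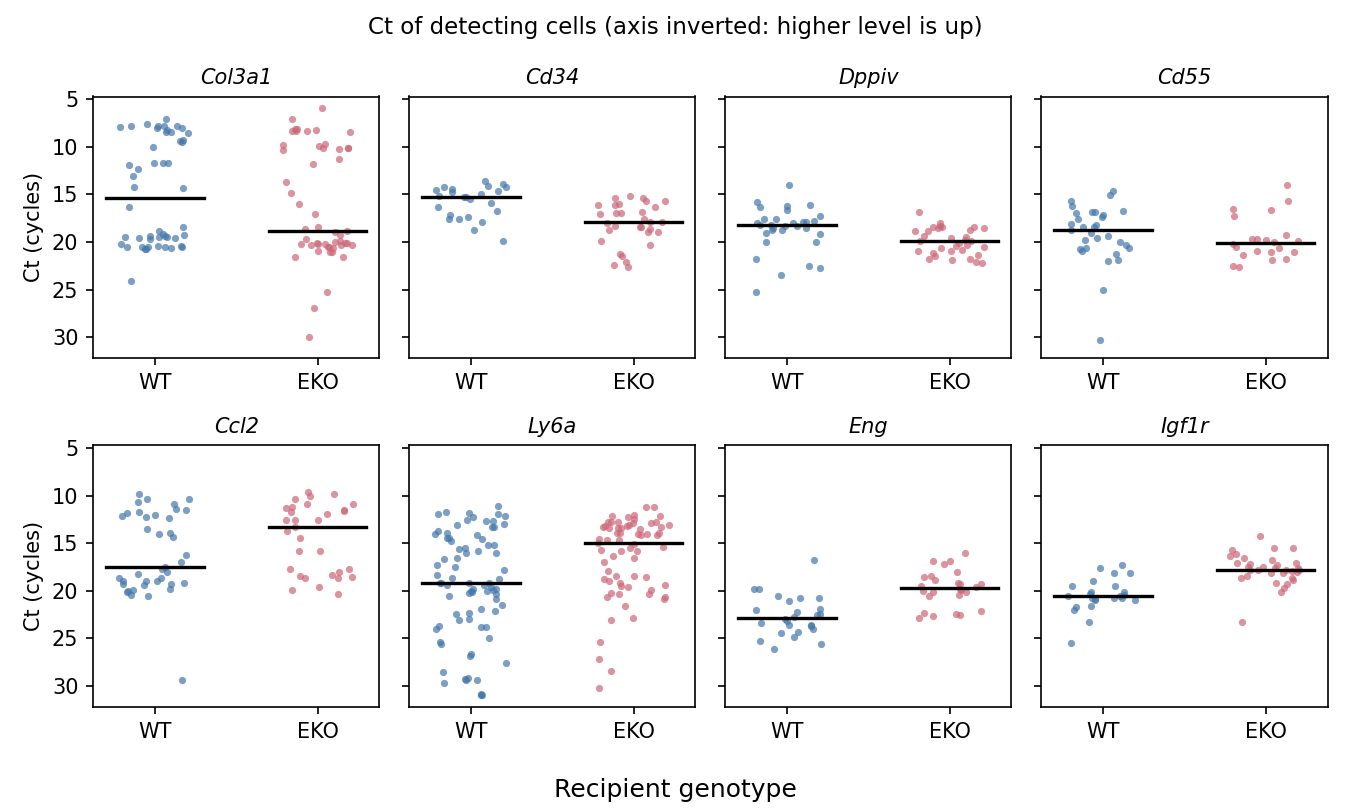
Ct of each detecting cell (points) for the 8 genes named by level, in cells with at least 10 assays detected; the axis is inverted so that higher levels lie up, and black lines are medians. Igf1r lies at 17.8 in EKO and 20.6 in WT cells, and Col3a1 forms an early and a late group in both genotypes.

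Of the gene lists, endothelial markers lay highest against random lists at the 10-assay filter. The median difference over the 10 measured endothelial markers was 8.89 points, at the 96.7 percentile of 10000 random lists of the same size and similar detection. It was 16.03 points in set A and -1.61 in set B: 4 markers were higher in EKO in both sets, 0 were lower and 6 were mixed or equal. Flt1, a receptor for vascular endothelial growth factor, was detected in 11 EKO cells (14.3%) and 3 WT cells (3.23%), with 24.04 points in set A and -2.22 in set B. Set A held 7 EKO cells that detected at least 4 of 6 endothelial markers. Vcam1, an adhesion molecule, differed by 16.6 points and Cd34 by 14.5. The remaining lists lay between the 9.77 and 80.2 percentiles. With at least 24 assays per cell the endothelial markers stood at 2.09 points, the 76.8 percentile, and stem cell transcription factors lay highest at 95.3. The median of that list was 3.66 points, and 0.00 without Sox2, which was detected in 19 of the 22 cells left out.

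Stem cell transcription factors differed by a median of 6.95 points over 8 assays, with 5 higher in both sets, among them Notch1, Myc (16.2 points) and Runx1 (15.2), a factor of blood development. All 5 cell cycle and survival genes were higher in both sets, with a median of 7.02 points, among them Bcl2 and Ccnd1 (7.02). Adhesion genes and integrins differed by 7.81 points, with 4 of 8 higher in both sets, including Icam1, Vcam1 and Itgb3 (11.9). The TGF-beta, Wnt and BMP list stood at 6.51 points with 5 of 7 higher in both sets, led by Ctnnb1, Wnt3a (13.2, and detected in 16 of the 22 cells left out) and Tgfbr1 (8.49). The 4 assays of the Cxcl12 axis had a median of 7.81 points, with -0.88 in set A and 14.8 in set B, and 1, Cxcr4, was higher in both sets. In cells with at least 24 assays the stem cell factors stood at 3.66 points (2 of 8 higher in both sets), the cell cycle list at 2.88 (2 of 5), adhesion at 3.23 (3 of 8), TGF-beta, Wnt and BMP at -1.17 (1 of 7) and the Cxcl12 axis at 2.74 (0 of 4). Of the genes named here, Myc (-0.22), Runx1 (-2.70), Ccnd1 (-0.76), Itgb3 (-0.13) and Tgfbr1 (-8.27) turned negative there.

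Progenitor surface markers had a median of 3.44 points, with 4 of 9 higher in both sets, and their leading members were Cd34, Thy1 (14.3) and the melanoma cell adhesion molecule Mcam (11.1). Thy1 differed by -0.16 points in set A and 29.4 in set B, and by -11.6 among cells with at least 24 assays, where Cd34 stood at -2.43. Growth factor receptors stood at 3.76 points with 4 of 11 higher, led by Notch1, Igf1r and Flt1. Angiogenic growth factors stood at 4.89 with 4 of 12 higher, led by Pdgfa (8.95), Pdgfb (8.50) and Angpt1 (6.80). Matrix genes differed by 3.27 points, with 3 of 7 higher and 1, Col1a1 (-8.49 points), lower in both sets. The median over the matrix genes was -10.3 points in set A and 9.01 in set B. Among them Col3a1 differed by -10.3 points in set A and 36.3 in set B. Mesenchymal markers stood at 3.60 points, with 1 of 8 higher and 1 lower. Their median was -5.53 points in set A and 11.1 in set B. Myeloid and lymphoid markers stood at 3.94 over 3 genes, with 1 higher: the leukocyte gene Ptprc (6.65), beside Itgam (3.94) and Adgre1 (-0.81). The 3 reference genes had a median of 0.00 points. Among cells with at least 24 assays the progenitor surface markers stood at -8.09 points, at the 2.57 percentile, with 1 of 9 higher in both sets. There the growth factor receptors stood at -1.17 (0 of 11), the angiogenic factors at -0.13 (1 of 12), the matrix genes at -1.48 (1 of 7), the mesenchymal markers at -5.12 (0 of 8) and the myeloid and lymphoid markers at 2.79 points (2 of 3). With no filter on cells the Ptprc difference was -4.17 points.

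The other 5 lists had fewer than 3 measured genes. Hif1a, the oxygen-regulated transcription factor, was detected in 92.5% of WT and 88.3% of EKO cells, and in 2 of the 22 cells left out by the filter. As 19 of those 22 are EKO cells, counting them would widen the Hif1a difference. Ccl2 was detected in 41.9% of WT and 40.3% of EKO cells, and its receptor Ccr2 in 20.4% and 28.6%. Nfkb1, an inflammatory transcription factor, was detected in 79.6% of WT and 85.7% of EKO cells, and with no filter on cells in 77.1% and 68.8%. The epithelial gene Trp63 was detected in 1 WT and 4 EKO cells, and the panel held 0 erythroid or platelet markers.

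The sort held cells with haematopoietic, mesenchymal and endothelial markers in both genotypes. At least 2 of the 5 measured haematopoietic progenitor markers were detected in 45 of 77 EKO cells (58.4%, 46.6 to 69.6%) and 42 of 93 WT cells (45.2%, 34.8 to 55.8%). This class does not separate blood cells from cells rich in collagen transcript. Of the 45 cells called collagen-high below, 97.8% detected Ly6a, 97.8% Runx1 and 88.9% Cd34. At least 2 of 6 mesenchymal markers were detected in 46 EKO cells (59.7%, 47.9 to 70.8%) and 44 WT cells (47.3%, 36.9 to 57.9%). Their difference lay in set B, where 73.7% of EKO and 46.7% of WT cells qualified, against 46.2% and 47.9% in set A. The class includes late collagen signal: when Col1a1 and Col3a1 counted only below Ct 16, it held 25 EKO cells (32.5%, 22.2 to 44.1%) and 28 WT cells (30.1%, 21.03 to 40.5%), a difference of 2.36 points, with -12.3 in set A and 17.7 in set B. At least 2 of 6 endothelial markers were detected in 14 cells of each genotype (18.2%, 10.3 to 28.6%, of EKO and 15.1%, 8.48 to 23.97%, of WT), with 28.2% against 16.7% in set A and 7.89% against 13.3% in set B. At least 2 of 3 myeloid markers were detected in 10 cells of each genotype. The intervals of the genotypes overlapped for each of these 4 classes, which are counts of markers and not cell types, and a cell can belong to several. Among cells with at least 24 assays, the haematopoietic progenitor class held 43 of 53 EKO (81.1%, 68.03 to 90.6%) and 40 of 42 WT cells (95.2%, 83.8 to 99.4%), the opposite direction. The endothelial class (26.4% of EKO and 33.3% of WT) and the mesenchymal class (81.1% and 83.3%) turned as well. The fixed marker sets of the lymphoid, epithelial and erythroid classes had 0 measured genes.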

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

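All tests in this part were chosen after the values were seen. The 22 cells left out by the filter, which enter no share in the comparison, still gave signal. Cxcl12 Mm00445552_m1 and Rn18s were detected in 100% of them (exact 95% interval 84.6 to 100%), Sox2 in 86.4% (65.1 to 97.1%), Wnt3a in 72.7%, Actb in 63.6%, Col3a1 in 45.5%, Timp2 in 40.9%, Col1a1 in 22.7%, and Ccl2 and Col1a2 in 18.2% each. Ang, Nanog, Nog and Ly6a were detected in 1 of the 22 each.

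RNA of the sorted cell would come later in cells of low yield, and over 28 assays the median Ct was 2.84 cycles later in the 97 cells under 24 assays than in the 95 others. Sox2, Wnt3a and Cxcl12 Mm00445552_m1 shifted by -0.48, -0.10 and 0.36 cycles, a median of -0.10. This cannot decide on the cell's RNA, since the 3 were chosen after their values were seen and Ct covers detecting cells only. Icam1 (23.8 under 24 assays, 23.1 in the others) and Notch1 (23.9 and 23.02) also moved by under 1 cycle. A small shift by yield does not make Cxcl12 Mm00445552_m1 constant over cells, since it differed between the cell classes defined below. In WT and EKO its median Ct was 16.25 ± 1.68 and 15.08 ± 1.76 in collagen-high cells. In Ptprc-detecting cells it was 18.34 ± 0.47 and 17.84 ± 0.52. Detection of Sox2 and Wnt3a was not rarer at low yield: 85.6% and 74.2% under 24 assays, 77.9% and 65.3% in the others. Genomic DNA would reach all 6 assays that lie inside 1 exon, and the 4 at 1 of 22 speak against it, but a limit of fewer than 10 assays itself holds such counts down, so it stays open for Sox2 and Actb: over the 97 cells the median of these 6 was 67.01% detecting, against 2.06% for the 83 assays that span exons, which include Wnt3a and, with the highest share of 100%, Cxcl12 Mm00445552_m1. Of the collagens, Col1a1, Col1a2 and Col3a1 came 9.64, 10.3 and 10.9 cycles later than in cells with Col1a1 below Ct 16, a range of 1.22 cycles. In the cells called Ptprc-detecting below, which have at least 24 assays, they came 9.49, 9.97 and 10.65 cycles later. Free RNA from collagen-expressing cells would give such near-equal offsets. Low expression in the cell itself could give them too, so the source of the collagen signal stays open. What gives Sox2 and Wnt3a their steady Ct stays open, because no well without a cell was analysed here and no biological explanation was tested.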

How the results depend on the processing

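The Actb and B2m requirement, the stricter filter for levels and the limit on collagen Ct were the tests chosen after the data were seen; the others were fixed before. The share differences of the 10 genes named by share kept their sign under each alternative run. For each set alone the naming rule itself required this. Within a set, the 25% filter turned Notch1 (-5.56 points), Ctnnb1 (-4.37) and Igf1r (-0.40) in set B and Timp1 (-2.50) in set A. Ct limits of 35, 30 and 28 moved 1 of the values they gave, and both normalizations of levels and the mean left all 8 named levels with their sign. The 25% filter changed most. It took the median difference over assays from 5.70 to -0.07 points, the medians of assays detected to 46.5 in WT and 45 in EKO, and the haematopoietic progenitor class to -14.1 points. It took the endothelial class to -6.92 points, the mesenchymal class to -2.20, the progenitor surface list to -8.09, the TGF-beta, Wnt and BMP list and the growth factor receptor list each to -1.17, and the angiogenic list to -0.13; the mesenchymal list stood at -5.12 and the matrix list at -1.48. In all, 6 lists and 14 named genes changed sign: Col3a1, Cd34, Dppiv, Ly6a, Eng, Ackr3, Thy1, Ccr2, Itgb3, Tgfbr1, Myc, Runx1, Ccnd1 and Adgre1. This filter leaves 42 WT and 53 EKO cells of similar median yield, with lower quartiles of 38 assays in WT and 33 in EKO. The cause of each change was not tested. Tercile weights gave a median over assays of 1.22 points, and -0.05 for the TGF-beta, Wnt and BMP list, -0.68 for progenitor surface markers, -0.94 for myeloid and lymphoid markers and -0.44 for mesenchymal markers, and Ly6a, Eng, Ackr3, Nfkb1, Tgfbr1 and Ptprc changed sign. With no filter on cells the median over assays was 1.04 points, the myeloid and lymphoid list stood at -2.08, and Ly6a (-14.6), Nfkb1 (-8.33) and Ptprc (-4.17) changed sign. The requirement of a detected reference gene removed 0 cells and gave those same values. The Cxcl12 axis, matrix and mesenchymal lists changed sign in set A alone, and the endothelial list in set B alone. In set A alone the mesenchymal class differed by -1.76 points, and in set B alone by 27.02, while the endothelial class differed by -5.44 in set B. The cause was not tested. Counting Col1a1 and Col3a1 only below Ct 16 took the mesenchymal class to 2.36 points, with -12.3 in set A and 17.7 in set B. Counting failed reactions at Ct 40 turned Col3a1 to -0.31 cycles, and gave no value for 6 of the 8 named levels because both medians were 40. The number of cells per genotype and set, 38 to 48 after filtering, limits each share.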

Other observations

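The tests and classes in this part were chosen after the values were seen, except the 2 other filters on yield, which were fixed before. Among the 95 cells with at least 24 assays detected, Col1a1 split into an early group, up to Ct 14.2, and a late group from Ct 17.04, with 0 cells within 1 cycle of a limit at 16. The 45 cells below that limit with fewer than 4 endothelial markers, called collagen-high here, detected Pdgfra, a fibroblast receptor, in 100%, Thy1 in 97.8% and Ackr3 in 95.6%. They are not free of the leukocyte marker Ptprc: 31 of the 45 (68.9%) also detected it, at a median Ct of 16.7 against 16.03 in the Ptprc-detecting class. Runx1 and Ly6a were each detected in 97.8% of the 45 and Cd34 in 88.9%, against 71.05%, 81.6% and 7.89% of the Ptprc-detecting class. The collagen-high cells also held each of the detections of Cxcl12 Mm00457276_m1 (21 of 45 cells, 46.7%) among these 95 cells. It was detected in 13 of the 21 EKO cells of this class (61.9%, 38.4 to 81.9%) and 8 of the 24 WT cells (33.3%, 15.6 to 55.3%). The difference was 24.8 points in set A and 46.03 in set B. Of the 38 Ptprc-detecting cells outside both other classes 0 detected Cxcl12 Mm00457276_m1, which allows up to 7.89%. These 38 cells detected Cd48 in 92.1%, the proliferation gene Mki67 in 50% and Birc5 in 47.4%, and Cxcr4 in 68.4% against 31.1% of the collagen-high cells. Collagen-high cells made up 24 of 42 WT cells (57.1%, 40.96 to 72.3%) and 21 of 53 EKO cells (39.6%, 26.5 to 54%), at 62.5% and 28% in set A and 50% of each genotype in set B.

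Within the collagen-high cells, Timp1 stood out: its median Ct was 10.6 ± 2.92 (SD, 21 cells) in EKO and 15.8 ± 2.26 (23 cells) in WT, a difference of -5.20 cycles, with -4.85 in set A and -4.62 in set B. The median over 47 assays with a level there was -0.71 cycles, so Timp1 lay -4.48 cycles from it. Nanog (-4.24 cycles, read by a single-exon assay), Igf1r (-3.19), the fibronectin receptor subunit Itga5 (-3.03) and Vegfa (-2.89) were also earlier in EKO in both sets, and Cd34 (2.62) and Cd55 (2.35) later. The Nanog SDs, 4.43 cycles in EKO and 4.30 in WT, were as large as its difference. Its median Ct also shifted by -2.52 cycles in cells under 24 assays against the others. In all, 18 assays of the collagen-high cells met a size of 1 cycle earlier and 2 later. Icam1 was detected in 20 of 21 EKO and 15 of 24 WT cells of this kind, and Tek in 3 and 11; in the Ptprc-detecting cells Icam1 went the other way, with 14 of 24 EKO and 10 of 14 WT cells. Within the Ptprc-detecting cells, Kit, the stem cell factor receptor, was detected in 6 of 24 EKO cells (25%, 9.77 to 46.7%) and 11 of 14 WT cells (78.6%, 49.2 to 95.3%), lower by about the same in each set (-51.1 and -51.3 points). Bcl2 was detected in 13 of 24 EKO cells (54.2%, 32.8 to 74.5%) and 2 of 14 WT cells (14.3%, 1.78 to 42.8%). It was the only assay higher in EKO there by 20 points with the same sign in both sets, while 8 were lower: Kit, Col1a2, Itga5, Ccnd1, Ccr2, Ly6a, Ctnnb1 and Fgfr1. These EKO cells also detected fewer assays, with a median of 32.5 against 36.5 in WT, and these shares were not adjusted for that.

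The size of the general gain in detecting cells in EKO depended on the filter on cells. With no filter the median difference over assays was 1.04 points, against 5.70 at the 10-assay limit, which removes 19 EKO and 3 WT cells of very low yield. Counting cells with so few assays lowers most EKO shares whatever the cause, so this fall cannot show that the filter made the gain. With no filter the median EKO cell still detected 28 assays and the median WT cell 20. Those medians lie on either side of the 24-assay limit, which 55.2% of EKO and 43.8% of WT cells reached, with overlapping intervals. On each side of it the median EKO cell detected fewer assays, 11 against 16.5 below and 45 against 46.5 above. The medians of 28 and 20 therefore do not show a gain in each EKO cell. Among cells with at least 24 assays the difference was -0.07 points, but that filter itself evens out the number of assays per cell, so the value cannot show whether yield is the cause. A change with recipient genotype in how many genes a recruited cell expresses cannot be told apart from a difference in sorting or lysis, because there is only 1 sample per genotype.

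Cells with at least 4 of the 6 endothelial markers numbered 7 of 25 EKO cells in set A (28%, 12.1 to 49.4%), 1 of 24 WT cells in set A, 1 of 18 WT cells in set B and 0 of 28 EKO cells in set B. The last allows up to 10.7% by the limit of 3 counts and 12.3% by the exact interval, which overlaps that of set A EKO. Over these 9 cells Pecam1 had a median Ct of 12.4 and Cdh5 of 14.2. The nitric oxide synthase gene Nos3 and Angpt2 were detected in 8 each. The 4 that detected Ptprc were all set A EKO cells. The set A WT cell was also rich in collagen transcript, with Col1a1 at Ct 6.74 and Col3a1 at 7.07. It detected 61 assays but lacked Tie1 and Nos3. The median of the class was 56 assays, against 45 in the other cells with at least 24 assays. A second cell in a well could give such values. Of the 48 EKO cells of set A, 41 detected 0 to 2 of the 6 markers, 0 detected 3 or 4, and 7 detected 5 or 6. Free RNA spread evenly over the wells is argued against, but only as the source of the strong signal in these cells. Copies were counted from the earliest Ct outside these cells, at one doubling per cycle, with the cells' own signal included. An even spread would leave at most 8.69 of the 48 wells without Flt1 and 0.00 without Cdh5, and 37 and 39 lacked them. Tie1 had no Ct outside these cells, so its copies were not counted. Because these cells were picked by the same markers, the count cannot decide on free RNA at a low level in the other wells. RNA held in a fragment or a second cell of a well was not tested, endothelial cells of the recipient that passed the gate could be a source since 0 panel assays read GFP, and recipient genotype stays open as well, since the share in EKO was 28% in set A and 0.00% in set B.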
